A study of Populus tomentosa with 9 samples.

How the data were processed

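RNA sequencing had been carried out on 9 libraries of Populus tomentosa suspension cells, 1 for each combination of 3 cell lines (wild type, antisense, overexpression) and 3 treatments (control, H2O2, ASA). The source and organism labels give poplar suspension cells, whereas the extraction protocol in the labels speaks of Arabidopsis stems. These labels contradict each other, and poplar is taken here from the sample labels and POPTR identifiers. Each library was placed in its group by its title. The design text of the series states that there were no replicates, so no condition has a measured replicate spread.

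Per the submitters' processing notes, Bowtie2 2.2.3, TopHat2 2.0.12, TopHat and HTSeq 0.6.1 were used. The roles of these tools and the genome build are not given in the sources used here. The deposited table of FPKM values (fragments scaled to gene length and to mapped reads) was made by the authors and covers 41624 genes, of which 41377 carry POPTR identifiers and 247 carry other identifiers. The authors also deposited 6 tables that compare each transgenic line with the wild type within a treatment. Per the file headers these hold scaled read values per library (a signal with no stated scale), log2 fold changes and q-values. The deposited tables contain only genes with an absolute log2 fold of at least 1 and a q-value of at most 0.00498, and the test and scaling behind them are not given in the sources used here. The ratio of the deposited signal values was used only to check the deposited log2 folds.

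The deposited comparison tables pair gene identifiers with protein domain descriptions. They cover 2976 genes, so a gene has a description only if the authors had listed it as different in at least 1 of their comparisons. Of these, 2719 have a product or domain description. None of the identifiers matched the reference table of gene names (0 matched), no coordinates were used, and genes are named by identifier and deposited description.

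FPKM values were examined for the step that 1 read is worth in each library. All 33158 genes with a value above 0 gave whole reads within a relative tolerance of 5e-09, which is 100% of them, although for the 1546 genes with reads in 1 library only this fixes no ratio. Summed recovered reads departed from the step ratio by at most 0.0922%. These reads gave the depth of each library, counting intervals and a floor of 3 reads, all of which cover counting error only. Reads shared between near-identical gene copies could not be told apart in the deposited values.

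The main test used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with line and treatment as factors over all 9 libraries, empirical Bayes moderation with a trend on mean expression, and Benjamini-Hochberg adjustment with a threshold of 0.05. Differences are therefore on the log2(FPKM + 1) scale, which understates the change of genes with low values. Genes with a mean of at least 1 FPKM were tested, 23350 in all, and chance alone gives 0.05 of them an unadjusted p below 0.05. The fit leaves 4 residual degrees of freedom, to which moderation adds 3.309. With no replicates, this residual is the scatter of a line effect over treatments (or of a treatment effect over lines), and each genotype is a single cell line. A gene passed only if its difference was large against that scatter. Written SD values are over the 3 libraries of a line or treatment, and thus include the other factor.

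Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, against the 2975 tested genes that have a deposited annotation, with adjustment over the 55 lists tested in each contrast. Before the data were examined, 32 lists were fixed as word patterns. Of these 15 had at least 5 described members and were tested, and 7 had none, among them ascorbate peroxidase. A further 40 lists were written in the wording of the deposited descriptions after those had been read and before any list was tested. Because only genes the authors had listed carry descriptions, no list is independent of these samples. Camera was repeated with an estimated correlation, and limma's fry was run over the same fit. Fry tests whether the genes of a list move on balance one way and does not compare them with other genes, so its result is no repeat of a camera call. Counts adjusted over the list alone use the members of that list only.

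Comparisons of 2 libraries were given without a test, as the number of genes differing by at least 2-fold on the log2(FPKM + 1) scale with at least 1 FPKM in the higher library. The median of a list in such a comparison was placed among 10000 random lists of the same size, drawn from annotated genes matched in 20 bins of mean expression. That percentile describes the libraries and is not a test of the conditions. Intervals for ratios of 2 libraries are exact 95% intervals for read counts.

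Named genes were chosen by a rule fixed before the data were examined. For each transgenic line against wild type and each treatment against control, the rule takes the 10 highest and 10 lowest differences among genes past the threshold that have the same sign in all 3 pairs of libraries and a deposited description. Genes without a description were passed over, so ranks hold among described genes (13 of the 19 genes past the threshold for antisense against wild type and 363 of the 668 for overexpression). Where fewer passed, the places were filled by the described genes whose smallest pairwise difference was largest, and these are stated not to have passed. For lists past the threshold, 4 members of largest difference were named. Reading "description" as a product or domain description, the extension of the member rule to the added SPX and chalcone synthase lists, and the limitation of 2-library comparisons to the first 2 of the 5 genes per direction were decided after values had been seen.

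Alternatives covered the pseudocount (0.1 and 5 FPKM), the filter (none, or a mean of at least 5 FPKM), median-ratio and quantile scaling, moderation without a trend, a fit without the other factor, a fit to the 6 libraries compared, and leaving out each library, each line and each treatment. Limma voom on the recovered reads and a fit without the antisense H2O2 and ASA libraries were added after the data had been seen. Unchanged groups were simulated 100 times against shared control libraries, and unchanged lines against shared wild type libraries for the overlap of calls, taking as many top-ranked genes per direction as had passed. The main test was tested on simulated data for overexpression against wild type. It recovered 20% of 100 genes given a 2-fold change and 63% of 100 genes given a 4-fold change, with 3 false calls among 23150 unchanged genes. A simulation of antisense against wild type with no effect gave 0 calls. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.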

Results

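Transcript levels were measured by RNA sequencing in suspension-cultured cells of Populus tomentosa, a poplar native to China. The 9 libraries crossed 3 cell lines with 3 treatments, with 1 library per condition and no replicates. The lines were a wild type and lines with an antisense or an overexpression construct. The labels do not name the gene targeted by the constructs, so its level cannot be given as a check of the lines. Cells 5 days after subculturing were kept as controls or exposed for 3 h to 10 mM H2O2, a reactive oxygen species, or to 1 mM ASA, an abbreviation the labels do not spell out. Recovered read totals ranged from 17102469 in the antisense control to 19629543 in the overexpression control, and a floor of 3 reads in a gene of 1 kb corresponded to 0.153 to 0.175 FPKM. Between 22584 and 23263 genes per library reached 1 FPKM, and the 20 most abundant genes took 3.73% to 5.57% of the reads. No pair of libraries was identical.

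The first principal component of log2(FPKM + 1) held 40.1% of the variance, and on it the overexpression H2O2 library (87.4) and the overexpression ASA library (70.6) lay apart from the other 7, which spanned -34.3 to -6.59. The second component (24.1%) set the wild type H2O2 library (30.3) and the library labelled antisense ASA (64.9) against the wild type ASA library (-44.0), the wild type control (-31.0) and the overexpression ASA library (-40.9). Across genes, which are not independent replicates, the H2O2 minus ASA difference in wild type correlated with that in the antisense line at -0.838 and with that in the overexpression line at 0.622. The antisense and overexpression lines correlated at -0.577.

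**Figure D1:**
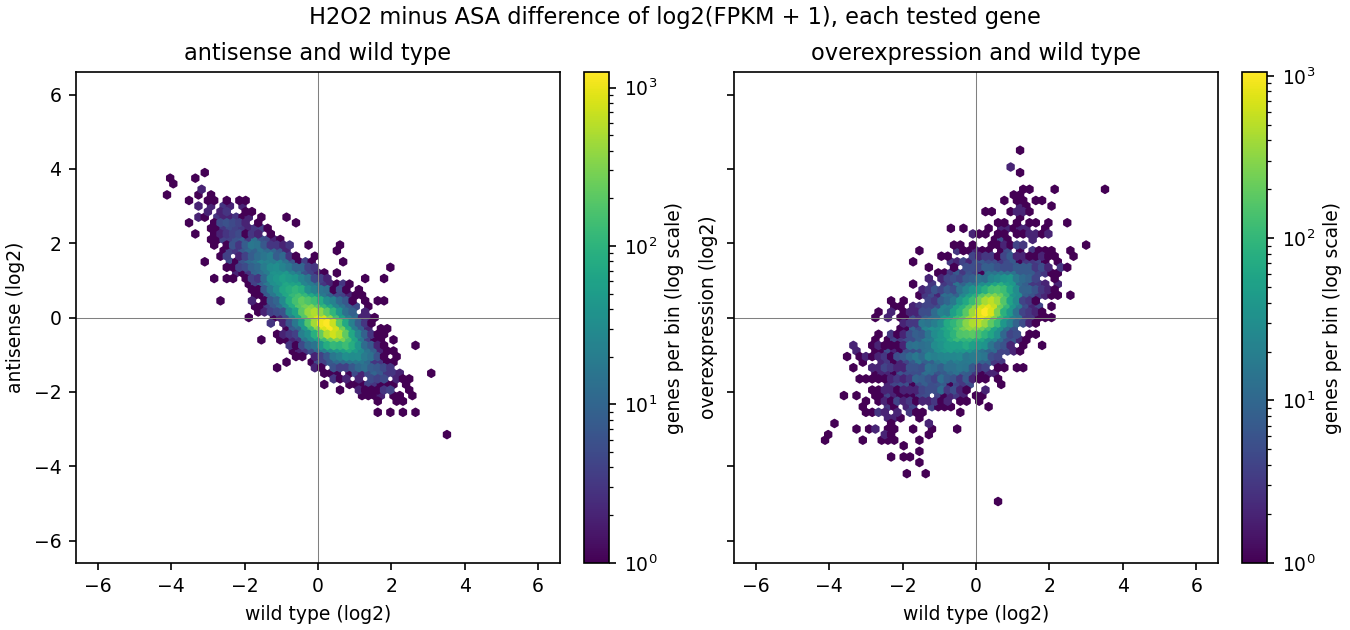
Each hexagon counts genes (colour, log scale) by the H2O2 minus ASA difference of log2(FPKM + 1) in wild type (x axis) and in the antisense or overexpression line (y axis), over 23350 genes and 1 library per condition. The points slope downward for the antisense line (correlation -0.838) and upward for the overexpression line (0.622).

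The first question was how the overexpression line differs from wild type across the 3 treatments. Among genes with a deposited description, the 3 that rose most are described as MADS-box or K-box transcription factors, of a family known for roles in flowering and meristem identity. POPTR_0011s03140 (K-box) rose by 5.46 ± 0.25 (log2, SE; limma adjusted p = 0.000296), from 0.145 ± 0.168 to 52.0 ± 22.4 FPKM (SD over 3 libraries), and POPTR_0013s09960 (MADS-box) rose by 5.35 ± 0.28 to 61.9 ± 4.96 FPKM. POPTR_0013s09980 (K-box) rose by 5.23 ± 0.19 and the WRKY gene POPTR_0005s08860 by 4.47 ± 0.18, to 36.1 ± 4.38 FPKM. The described gene with the largest loss was POPTR_0003s02940, a PHOSPHO2-type phosphatase by its description, which fell by 5.09 ± 0.64, from 531 ± 290 to 36.3 ± 54.8 FPKM (adjusted p = 0.0127), and the glycerophosphodiester phosphodiesterase POPTR_0001s33270 fell by 5.08 ± 0.67.

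The naming rule takes described genes only, 363 of the 668 past the threshold, and 4 higher and 6 lower genes without a description lay beyond the smallest difference named here. The other genes taken by the rule on the higher side of this comparison were the glycine-rich cell wall protein Novel00190 (3.53 ± 0.23), the transferase POPTR_0008s06520 (3.37 ± 0.51), POPTR_0013s08910 with a translation initiation factor SUI1 domain (3.16 ± 0.30), the shikimate dehydrogenase POPTR_0013s03080 (2.97 ± 0.33), the GDSL lipase POPTR_0306s00200 (2.93 ± 0.43) and POPTR_0006s15720, whose description includes cytokinin dehydrogenase (2.93 ± 0.22). On the lower side were the type 5 acid phosphatases POPTR_0012s03910 (-4.84 ± 0.72) and POPTR_0015s05350 (-4.04 ± 0.68), the SPX genes POPTR_0018s13140 (-4.66 ± 0.68), POPTR_0006s06880 (-4.31 ± 0.52) and POPTR_0176s00240 (-4.19 ± 0.53), the PHOSPHO2-type POPTR_0008s20130 (-4.58 ± 0.65), POPTR_0009s12160 of unknown function (-4.49 ± 0.63) and the BURP-domain gene POPTR_0129s00200 (-4.36 ± 0.28). All 20 passed, with adjusted p from 0.000162 for POPTR_0013s09980 to 0.0296 for POPTR_0015s05350, and all kept 1 sign in the 3 pairs of libraries.

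By gene group, SPX-domain genes, known as sensors and regulators of phosphate state, had a median of -3.72 in overexpression against wild type, and 8 of 9 members fell (8 also adjusted over the list alone). The member that did not fall was POPTR_0017s12260. Summed SPX values were 858 FPKM in the wild type control against 176 in the overexpression control, 496 against 47.7 after H2O2 and 553 against 38.4 after ASA. Ribosomal protein genes had a median of 0.92, with 40 members risen, 1 fallen and the rest of the 153 not past the threshold (132 higher and 1 lower adjusted over the list alone). Examples are the acidic protein P0 gene POPTR_0008s06620 (1.88 ± 0.30), the L29 gene POPTR_0008s04870 (1.81 ± 0.22), POPTR_0008s10960 of the L7Ae family (1.61 ± 0.24) and the L18e gene POPTR_0013s01520 (1.55 ± 0.30). This list includes 13 genes that carry the S5 fold or Hsp90 wording without being ribosomal proteins by name. Translation factors had a median of 0.82 with 4 of 20 members risen (10 higher and 1 lower adjusted over the list alone).

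Chalcone and stilbene synthases with chalcone isomerase, early enzymes of flavonoid synthesis, had a median of -1.71, and all 7 were lower in the overexpression line. Of these 3 fell (7 adjusted over the list alone), namely the isomerase POPTR_0010s21980 (-1.83 ± 0.31, adjusted p = 0.0298) and the synthases POPTR_0001s14310 (-1.74 ± 0.34, adjusted p = 0.0452) and POPTR_0014s14200, named CHS (-1.71 ± 0.21, adjusted p = 0.0110). POPTR_0001s14320 was at -1.92 ± 0.39 with adjusted p = 0.0524. Histone genes had a median of 0.68, with 18 of 19 higher and 1 past the threshold (2 adjusted over the list alone), the H1/H5-type POPTR_0008s13170 (1.14 ± 0.22). In the control libraries alone the histone median was -0.0912 with 9 of 19 higher, against 1.20 and 1.01 in the H2O2 and ASA libraries, which stand apart on the first component. The core histone genes POPTR_0008s03060 (1.15), POPTR_0013s01890 (1.15) and POPTR_0008s03040 (1.11) did not pass. Camera gave these lists adjusted p of 4.58e-35 (ribosomal), 4.03e-05 (SPX) and 0.00568 (chalcone, histone and translation factor), and for each the adjusted p = 0.933 with an estimated correlation. The fixed lists also included glutathione S-transferases (median -0.76, 1 fallen of 22, camera adjusted p = 0.0939) and cytochrome P450s (median -1.04, 2 risen and 5 fallen of 32, camera adjusted p = 0.136), neither past the threshold. The call was lost without wild type H2O2 for chalcone (adjusted p = 0.0667) and histone genes (0.0667), without overexpression H2O2 for histones (0.101) and without the overexpression control for translation factors (0.104). All list members had been chosen by the study on these samples, so their direction is not independent evidence.

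In total 668 of 23350 genes passed for overexpression against wild type, 245 higher and 423 lower, and 4565 had an unadjusted p below 0.05. This count moved with single libraries: it was 70 without the wild type ASA library, 72 without overexpression H2O2, 73 without wild type H2O2, 100 without overexpression ASA, 135 without the wild type control, 279 without the antisense control and 1478 without the overexpression control. It was 395 without both treated antisense libraries. The overexpression H2O2 and ASA libraries, which lie apart on the first component (87.4 and 70.6), enter every value above.

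**Figure D2:**
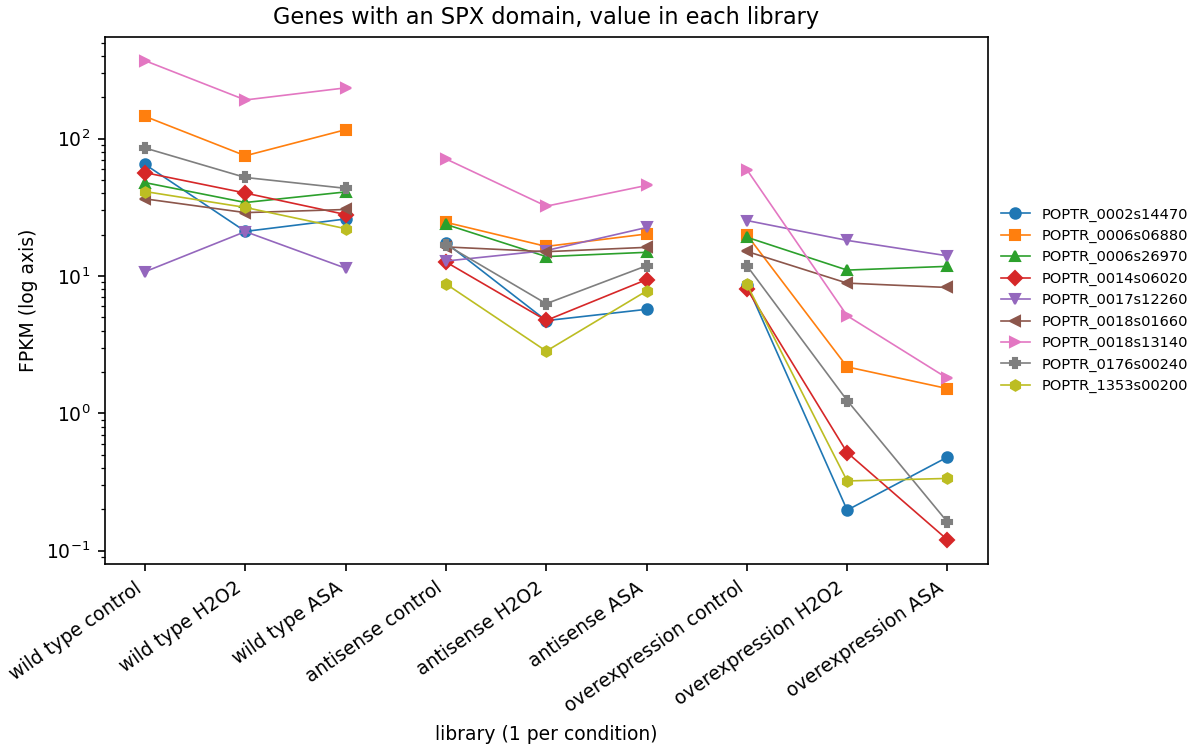
FPKM (log axis) of the 9 genes with an SPX domain in each of the 9 libraries, 1 per condition, with lines joining the 3 treatments of a cell line. All except POPTR_0017s12260 lie highest in wild type, and POPTR_0018s13140 goes from 369 FPKM in the wild type control to 1.80 in the overexpression ASA library.

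The second question was how the antisense line differs from wild type. The K-box gene POPTR_0011s03140 rose here too, by 3.84 ± 0.25 (adjusted p = 0.0184), to 15.9 ± 5.22 FPKM. Of the genes that fell, 3 carry the plant-specific BURP domain. Among them POPTR_0129s00200 and POPTR_0004s14410 have the same deposited gene name. Reads shared between near-identical copies could not be told apart, so these may not be separate signals. POPTR_0129s00200 fell by 2.61 ± 0.28, from 51.3 ± 3.87 to 8.04 ± 3.86 FPKM, POPTR_0004s14430 fell by 2.60 ± 0.23 and POPTR_0004s14410 fell by 2.22 ± 0.23. The expansin POPTR_0018s10730, of a family that loosens cell walls, fell by 1.94 ± 0.18, from 1005 ± 374 to 260.2 ± 87.9 FPKM. The type 5 acid phosphatase gene POPTR_0008s13870 fell by 2.42 ± 0.22 and the purple acid phosphatase gene POPTR_0009s12400 fell by 1.61 ± 0.18.

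The remaining genes named on the lower side were POPTR_0014s07740, described as a lipopolysaccharide-modifying protein (-2.51), POPTR_0019s13100 of unknown function (-2.11) and the CAP-domain genes POPTR_0473s00220 (-2.01) and POPTR_0473s00200 (-1.80). The 10 lower genes, named among described genes only, had adjusted p from 0.0301 for POPTR_0014s07740 to 0.0467 for POPTR_0129s00200. In all 19 genes passed, 3 higher and 16 lower, with 1785 at an unadjusted p below 0.05. Besides POPTR_0011s03140, the higher genes were POPTR_0011s03150 (2.34) and POPTR_0010s05790 (1.94), which have no description and are named here after their values were seen. All 19 also passed in the overexpression line with the same sign (3 higher and 16 lower). Independent lists of these sizes would share 0.0315 and 0.29, and simulated unchanged lines that share the wild type libraries 1.91 and 9.45 (at most 3 and 14 in 100 simulations), so part of this overlap may come from those libraries. Further genes taken by the naming rule were higher in all 3 pairs and did not pass: the permease POPTR_0010s10550 (1.98), myo-inositol-1-phosphate synthase POPTR_0005s08050 (1.89), the auxin efflux carrier POPTR_0015s04570 (1.92), the family 9 glycoside hydrolase POPTR_0009s12690 (1.62), POPTR_0012s08970 (1.95), the thaumatin POPTR_0009s03410 (1.77), POPTR_0010s16060 (1.47) and the receptor-type kinases POPTR_0008s18150 (1.37) and POPTR_0010s06270 (1.33).

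Among gene groups in antisense against wild type, the SPX list had a median of -2.13 with 8 of 9 members lower, none past the threshold over all genes (0) and 8 adjusted over the list alone. Summed SPX values in the antisense line were 204 FPKM in the control, 111 after H2O2 and 154 after ASA. The lowest members were POPTR_0018s13140 (-2.41), POPTR_0006s06880 (-2.37), POPTR_0176s00240 (-2.31) and POPTR_1353s00200 (-2.20). Ribosomal protein genes had a median of 0.41, and within treatments it was above 0 in the control and the library labelled antisense ASA but not in antisense H2O2. Of the 153 members 149 were higher and 0 were past the threshold by either adjustment. The furthest were POPTR_0013s11140 (L15e, 0.95), POPTR_0017s11850 (L34e, 0.83), POPTR_0005s10090 (0.74, a small GTP-binding protein with the S5 fold) and POPTR_0014s12340 (L22e, 0.71). Translation factors had a median of 0.36 with 18 of 20 higher. The list for hypoxia and sugar starvation had a median of -0.87 with all 9 members lower and 1 past the threshold adjusted over the list alone. It was led by the sucrose synthases POPTR_0017s02060 (-1.33) and POPTR_0018s07380 (-1.21) and the pyruvate decarboxylases POPTR_0011s07630 (-1.20) and POPTR_0016s12760 (-0.90). Camera passed these lists with adjusted p of 7.33e-07 (SPX), 1.35e-19 (ribosomal), 0.00397 (translation factor) and 0.00728 (hypoxia). Each had an adjusted p = 0.995 with an estimated correlation. Their members were listed by the study from these samples and are not independent evidence. Without the library labelled antisense ASA the hypoxia list had an adjusted p = 0.224 and translation factors 0.421, and without all 3 ASA libraries ribosomal proteins had 0.286.

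The antisense count rests on single libraries: it was 30 without the overexpression control, 1 without overexpression ASA and 0 without any one of the other 7, and 0 without the libraries labelled antisense H2O2 and antisense ASA, whose H2O2 minus ASA difference runs against wild type (-0.838). It was 3 with a pseudocount of 0.1, 0 without a filter, 7 among genes of at least 5 FPKM and 6 by voom on the recovered reads.

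Set directly against the overexpression line, the antisense line had higher SPX genes (median 1.79, 8 of 9 higher) and higher chalcone synthase and isomerase genes (median 1.17, 7 of 7), and lower histone genes (median -0.84, 18 of 19 lower), ribosomal protein genes (median -0.53, 141 of 153 lower) and wound-induced genes (median -0.63, 17 of 17 lower). Adjusted over the list alone, 7 SPX and 6 chalcone synthase members were higher, 7 histone members were lower and 1 higher, 25 ribosomal members were lower and 1 higher, and 0 wound-induced members passed. The summed SPX value of the antisense line was 1.16 times that of the overexpression line in the controls, 2.34 times after H2O2 and 4.01 times after ASA. Of 19 histone genes the authors' tables list 0 as higher in the overexpression control than in wild type, 12 after H2O2 and 9 after ASA (0, 1 and 0 lower). The overexpression H2O2 and ASA libraries stand apart on the first component. None of the examples passed over all genes. Among SPX genes they are POPTR_0018s13140 (2.25), POPTR_0006s06880 (1.94), POPTR_0014s06020 (1.91) and POPTR_0176s00240 (1.88), and POPTR_0010s21980 (1.39), POPTR_0001s14320 (1.32), POPTR_0001s14310 (1.26) and POPTR_0014s14200 (1.17) for flavonoid enzymes. Histone examples are POPTR_0008s03060 (-1.83), POPTR_0369s00200 (-1.74), POPTR_0004s03100 (-1.68) and POPTR_0013s01890 (-1.54). The ribosomal list was led by POPTR_0008s04870 (-1.32), POPTR_0008s06620 (-1.27) and the S28e gene POPTR_0008s01380 (-1.13), followed by POPTR_0005s26260 (-1.12), an Hsp90 chaperone. Camera gave adjusted p of 0.0136 for SPX, chalcone synthase and wound-induced genes, 0.000209 for histones and 6.23e-16 for ribosomal proteins, each with adjusted p = 0.905 with an estimated correlation. Without the library labelled antisense ASA the adjusted p was 0.256 for SPX, 0.165 for chalcone synthase and 0.749 for wound-induced genes. Without overexpression ASA it was 0.0638, 0.0638 and 0.310, and without the antisense control 0.0758 for chalcone synthase. These lists too were drawn from genes the study chose on the same samples. Here 85 genes passed, 34 higher and 51 lower, with 4136 at an unadjusted p below 0.05. Leaving out 1 library gave 2149 without the overexpression control and between 10 (without overexpression H2O2) and 31 (without wild type ASA) for each of the other 8, and 0 without both treated antisense libraries.

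Over all 3 lines at once, 333 genes differed (limma F test), with 4254 at an unadjusted p below 0.05 and 237 past the threshold by voom. Leaving out 1 library gave 1389 without the overexpression control, 382 without antisense ASA and between 33 (without overexpression H2O2) and 179 (without antisense H2O2) for each of the other 7. The log2 differences of the antisense and overexpression lines from wild type correlated across genes at 0.433, against 0.502 for simulated unchanged groups that share the wild type libraries. Their covariance was 0.0954 against a simulated 0.0595, and since 3 wild type libraries cannot be split into a pair of sets with at least 2 in each, part of any excess may come from the shared libraries.

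The third question was what H2O2 and ASA do across the lines. After H2O2 only POPTR_0019s13100, a plant gene of unknown function (DUF506), passed the threshold. It fell by 2.37 ± 0.18 (limma adjusted p = 0.0483). Its level went from 98.1 to 20.1 FPKM in wild type, 25.5 to 4.08 in the antisense line and 6.26 to 0.288 in the overexpression line. The call was lost in 8 of 9 fits without 1 library and in 12 of 13 other alternatives, voom among them. With 4 residual degrees of freedom, genes that did not pass cannot be called unchanged. The haem peroxidase POPTR_0003s21610 was at 280 ± 96.8 FPKM in controls and 46.0 ± 49.6 after H2O2 (-3.34 ± 0.56, adjusted p = 0.408). The FAD-linked oxidase POPTR_0011s16560, with a berberine-like domain, was at 1405 ± 246 FPKM in controls and 339 ± 285 after H2O2 (-3.20 ± 1.03, adjusted p = 0.677). On the higher side the family 17 glycoside hydrolase POPTR_0016s00460 was at 4.61 ± 1.97 in controls and 49.4 ± 31.8 FPKM after H2O2 (2.90 ± 0.43, adjusted p = 0.360), and the lipid transfer protein POPTR_0002s25240 was at 11.7 ± 5.65 and 44.9 ± 14.4 FPKM (1.91 ± 0.19, adjusted p = 0.110). Neither passed.

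The other genes named for H2O2 did not pass either, with adjusted p of at least 0.336, the value of POPTR_0017s02060. Higher in all 3 lines were POPTR_0015s15330, a phosphate-induced protein 1 (2.01), the kinase POPTR_0016s14210 named WNK5 (1.64), CTP synthase POPTR_0003s15650 (1.52), the family 9 glycoside hydrolase POPTR_0001s11430 (1.66), the organ-specific protein POPTR_0004s16060 (1.47), the peptidase POPTR_0005s20110 (1.05), the hydrophobic seed protein POPTR_0001s00400 (1.63) and the family 28 glycoside hydrolase POPTR_0008s09990 (1.53). Lower in all 3 were the SPX gene POPTR_0002s14470 (-2.09), the glycerophosphodiester phosphodiesterase POPTR_0001s13390 (-1.82), the sucrose synthase POPTR_0017s02060 (-1.76), POPTR_0003s02940 (-2.28), the nucleoside phosphorylase POPTR_0019s07690 (-2.09), the FAD-linked oxidase POPTR_0254s00230 (-3.12) and the phosphoesterase POPTR_0013s07120 (-1.46).

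For H2O2 against control the gene groups past the threshold by camera were ribosomal proteins (median 0.41, 143 of 153 higher, adjusted p = 1.37e-24), histones (0.59, 19 of 19 higher, 3.95e-08), glutathione S-transferases, enzymes of detoxification (-0.68, 20 of 22 lower, 2.99e-05), SPX genes (-1.44, 8 of 9 lower, 0.000149), thioredoxins and glutaredoxins (-0.50, 27 of 34 lower, 0.00224), AUX/IAA genes of auxin signalling (0.33, 14 of 17 higher, 0.0178), lipid transfer proteins (0.18, 8 of 13 higher, 0.0178) and hypoxia and sugar starvation (-0.61, 8 of 9 lower, 0.0356). Each had an adjusted p = 0.871 with an estimated correlation, and the members came from the study's own lists on these samples. The overexpression H2O2 library, which stands apart on the first component (87.4), had the median furthest from 0 in the histone, glutathione S-transferase, SPX and AUX/IAA lists, and whether the lines differ was not tested. In the wild type, antisense and overexpression lines the medians after H2O2 were -0.0418, 0.35 and 1.44 for histones, -0.48, -0.42 and -1.95 for glutathione S-transferases, -0.48, -1.12 and -2.58 for SPX genes and 0.00201, 0.13 and 0.99 for AUX/IAA genes. Without the 3 overexpression libraries the call was lost for glutathione S-transferases and thioredoxins (adjusted p = 0.0559 for both), lipid transfer proteins (0.125) and AUX/IAA genes (0.941). The AUX/IAA list turned the other way without the overexpression control (adjusted p = 0.949) and was lost without overexpression H2O2 (0.204). SPX was lost without antisense H2O2 (0.104), lipid transfer proteins without antisense H2O2 (0.118) or the overexpression control (0.192), and hypoxia without either of the wild type or antisense control and H2O2 libraries (0.163 to 0.513). No member passed over all genes (0). Adjusted over the list alone, 7 SPX members and 1 hypoxia member were lower, 5 lipid transfer proteins were higher and 1 lower, 1 AUX/IAA member was lower against the list's direction, and 0 passed in the other 4 lists. Of the 34 thioredoxin and glutaredoxin entries 20 are glutathione S-transferases, and a stricter list of 11 such entries was not past the threshold. Examples are the glutathione S-transferases POPTR_0019s15090 (-2.05), POPTR_0019s15100 (-1.76), POPTR_0010s07070 (-1.41, from 2595 ± 61.7 to 1093 ± 546 FPKM) and POPTR_0006s02510 (-1.28). Others are the histone H2A genes POPTR_0002s04720 (1.13), POPTR_0005s02660 (0.95) and POPTR_0005s23810 (0.94) with the H4 gene POPTR_0007s14090 (0.81), the ribosomal protein genes POPTR_0008s06620 (0.85), POPTR_0008s19110 (0.78), POPTR_0003s11430 (0.76) and POPTR_0012s02860 (0.75). Further examples are the SPX genes POPTR_0018s13140 (-1.79), POPTR_1353s00200 (-1.53) and POPTR_0176s00240 (-1.51), and the starvation genes POPTR_0025s00740 (-0.95), POPTR_0017s00800 (-0.82) and POPTR_0004s05330 (-0.81).

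ASA changed no gene past the threshold (0 by limma on log2 values, with 1325 at an unadjusted p below 0.05, and 2 by voom on recovered reads). The voom calls, named after their values were seen, were POPTR_0009s11560 (2.41, adjusted p = 0.0484) and the nucleoside phosphorylase POPTR_0019s07690 (-3.49, adjusted p = 0.0351). The peroxidase POPTR_0003s21610 was at 43.4 ± 42.6 FPKM after ASA (-3.31, adjusted p = 0.451), and POPTR_0011s16560 and POPTR_0254s00230 were at -3.29 and -3.33. POPTR_0002s25240 was at 45.0 ± 20.3 FPKM (1.84, adjusted p = 0.142) and POPTR_0016s00460 at 55.7 ± 42.4 FPKM (2.91). None of the named genes passed, and the smallest adjusted p among them was 0.107 for POPTR_0019s13100 (-1.92).

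Also higher after ASA in all 3 lines, without passing, were the bHLH gene POPTR_0006s03590 (1.30), the family 1 glycoside hydrolase POPTR_0001s23430 (1.08), POPTR_0001s00400 (1.78), the kinesin POPTR_0013s02150 (1.01), WNK5 POPTR_0016s14210 (1.55), POPTR_0004s16060 (1.29), the family 28 glycoside hydrolase POPTR_0010s16180 (1.25) and the amino acid transporter POPTR_0005s20400 (1.02). Lower were the NmrA-like POPTR_0009s12070 (-1.93), the NAM gene POPTR_0004s18860 (-1.79), the SPX gene POPTR_0002s14470 (-1.82), the acid phosphatase POPTR_0008s13870 (-1.80), POPTR_0019s07690 (-2.04) and the small heat shock gene POPTR_0008s06260 (-1.38).

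Gene groups past the threshold by camera for ASA against control were histones (median 0.88, 19 of 19 higher, adjusted p = 9.01e-14), ribosomal proteins (0.24, 124 of 153 higher, 3.30e-10), SPX genes (-1.29, 8 of 9 lower, 3.46e-05), glutathione S-transferases (-0.73, 18 of 22 lower, 0.00127), HSP70 and HSP90 chaperones (-0.54, 20 of 20 lower, 0.00127), heat shock and chaperone genes as a whole (-0.41, 43 of 51 lower, 0.00128), small HSP20 genes (-0.77, 6 of 7 lower, 0.00185), lipid transfer proteins (0.37, 8 of 13 higher, 0.00302), ERF transcription factors (-0.42, 25 of 31 lower, 0.00535), hypoxia and sugar starvation (-0.71, 8 of 9 lower, 0.00771), AUX/IAA genes (0.39, 15 of 17 higher, 0.00771), thioredoxins and glutaredoxins (-0.33, 24 of 34 lower, 0.0213) and haem peroxidases (-0.39, 14 of 18 lower, 0.0332). Each list had an adjusted p = 0.847 or an adjusted p = 0.858 with an estimated correlation, and none is independent of the study's own choice of genes on these samples. In the wild type, antisense and overexpression lines the medians after ASA were 0.73, 0.21 and 1.74 for histones, -0.65, -0.39 and -2.86 for SPX genes, -0.0071, -0.85 and -1.10 for glutathione S-transferases and -0.19, 0.16 and 1.21 for AUX/IAA genes. Without the 3 overexpression libraries, of which the H2O2 and ASA libraries stand apart on the first component, the call was lost for haem peroxidases (adjusted p = 0.301) and lipid transfer proteins (0.0947), and the AUX/IAA list turned (0.947). Without the library labelled antisense ASA the call was lost for ribosomal proteins (adjusted p = 0.973), glutathione S-transferases, lipid transfer proteins, ERF, hypoxia, AUX/IAA, thioredoxin and peroxidase genes. It was lost without overexpression ASA for the 3 chaperone lists, AUX/IAA and peroxidases, and without wild type ASA for HSP70 and HSP90, thioredoxins and peroxidases. It was lost without the overexpression control for glutathione S-transferases, lipid transfer proteins, thioredoxins and peroxidases, without the antisense control for heat shock genes and hypoxia, and without the wild type control for hypoxia. The AUX/IAA list turned the other way without the overexpression control (adjusted p = 0.860). As for H2O2, the stricter list of 11 thioredoxin and glutaredoxin entries was not past the threshold. Over all genes 0 members passed. Adjusted over the list alone, 3 histones were higher, 5 SPX genes, 2 heat shock genes, 2 small HSP20 genes, 2 haem peroxidases, 1 glutathione S-transferase, 1 ERF and 1 hypoxia gene were lower, 5 lipid transfer proteins were higher and 1 lower, and 1 AUX/IAA gene was lower against its list.

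Among the members for ASA, the HSP70 genes POPTR_0001s03410 (-2.04), POPTR_0008s05410 (-1.71), POPTR_0010s21350 (-1.62) and POPTR_0010s21280 (-1.52) stood lowest of the chaperones, the last at 92.8 ± 2.13 FPKM in controls and 38.8 ± 25.8 after ASA. Histones were led by the H2A genes POPTR_0002s04720 (1.11), POPTR_0005s02660 (1.01) and POPTR_0001s44140 (0.95) and the H2B gene POPTR_0008s02990 (0.95). Glutathione S-transferases were led by POPTR_0010s07070 (-1.18), POPTR_0019s15090 (-1.13), POPTR_1996s00210 (-1.01) and POPTR_0019s15100 (-0.98). SPX genes were led by POPTR_0018s13140 (-1.91), POPTR_0176s00240 (-1.64) and POPTR_0014s06020 (-1.47), and starvation genes by POPTR_0017s02060 (-1.74), POPTR_0017s00800 (-0.90), POPTR_0004s05330 (-0.89) and POPTR_0016s12760 (-0.81). Ribosomal protein genes reached 0.55 (POPTR_0008s19110), 0.54 (POPTR_0014s10120, POPTR_0016s08070 and POPTR_0018s02260).

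The H2O2 and ASA libraries were also set against each other. HSP70 and HSP90 genes were higher after H2O2 than after ASA (median 0.64, 20 of 20, camera adjusted p = 5.71e-18), as were heat shock genes as a whole (0.29, 36 of 51, 4.13e-09), small HSP20 genes (0.45, 5 of 7, 0.000263), ribosomal proteins (0.17, 151 of 153, 1.37e-14), translation factors (0.16, 18 of 20, 0.0135), multicopper oxidases (0.28, 7 of 8, 0.0227) and chalcone synthases (0.23, 7 of 7, 0.0243). UDP-glycosyltransferases (-0.25, 24 of 34 lower, 0.0135), which make up the whole detoxification list, bZIP factors (-0.43, 10 of 12, 0.0139), histones (-0.20, 17 of 19, 0.0262) and glutathione S-transferases (-0.23, 17 of 22, 0.0262) were lower. The 3 chaperone lists and the oxidases had an adjusted p = 0.740 with an estimated correlation, and the other 8 lists, counting detoxification apart, an adjusted p = 0.944 with an estimated correlation. No member passed over all genes or adjusted over the list alone (0), no list is independent of the study's choice of genes, and limma called 0 genes, with 84 at an unadjusted p below 0.05 and 0 by voom. Of the 12 lists, only the HSP70 and HSP90 list kept its call without any one of the 6 libraries of these treatments. It alone kept it without the 3 libraries of any one line. That list did not behave alike in the 3 lines: its median against control was 0.0443 after H2O2 and -0.84 after ASA in wild type, 1.01 and -1.18 in the overexpression line, and -0.77 and -0.11 in the antisense line, which ran the other way. Without the 3 overexpression libraries the call was lost for heat shock genes as a whole (adjusted p = 0.126), small HSP20 genes (0.327), translation factors (0.738), oxidases (0.129), chalcone synthases (0.301) and bZIP factors (0.542), and without the 3 wild type libraries the ribosomal list turned (0.339). Among single libraries, the side turned for chalcone synthases without wild type H2O2 (adjusted p = 0.933), for glutathione S-transferases (0.116) and glycosyltransferases (0.548) without overexpression H2O2 and for histones without overexpression ASA (0.945). The antisense line runs against the others here (correlations -0.838 with wild type, -0.577 with overexpression). That raises the residual, so 0 calls do not show that H2O2 and ASA act alike.

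Among the members of those lists were the HSP70 genes POPTR_0001s03420 (1.70), POPTR_0001s03410 (1.63) and POPTR_0010s21270 (1.40) and the HSP20 gene POPTR_0009s05440 (1.39), the Hsp90 genes POPTR_0004s07190 (0.70) and POPTR_0016s00510 (0.50), which the ribosomal list holds for their S5 fold, the P0-like POPTR_0001s46440 (0.47) and the S25 gene POPTR_0010s24580 (0.44). Chalcone synthases POPTR_0001s14320 (0.47), POPTR_0001s14310 (0.39) and POPTR_0003s17530 (0.23) and the isomerase POPTR_0010s21980 (0.23) were higher after H2O2. Lower were the glycosyltransferases POPTR_0006s05450 (-1.002), POPTR_0001s31140 (-0.92), POPTR_0014s14300 (-0.92) and POPTR_0015s08330 (-0.75), the glutathione S-transferases POPTR_0019s15090 (-0.91), POPTR_0019s15100 (-0.78), POPTR_0006s02510 (-0.53) and POPTR_0008s17520 (-0.49), and the histones POPTR_0001s44140 (-0.46), POPTR_0009s03310 (-0.40), POPTR_0013s01890 (-0.36) and POPTR_0010s23720 (-0.30).

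Over the 3 treatments at once, 0 genes passed limma's F test, with 979 at an unadjusted p below 0.05 and 0 by voom. Across genes, the H2O2 and ASA differences from control, as means over the 3 lines, correlated at 0.815, against 0.5003 for simulated unchanged groups that share the controls. The covariance was 0.110 against a simulated 0.0593, and part of any excess may come from the shared control libraries. Within single lines, where the control is shared too, the correlation was 0.332 in wild type, 0.361 in the antisense line and 0.724 in the overexpression line. All are below the 0.815 of the means. The H2O2 minus ASA difference of the antisense line runs against wild type (-0.838), and averaging over lines cancels part of it. The 0.815 therefore does not show that H2O2 and ASA act alike. The H2O2 count was 1 without the library labelled antisense ASA and 0 without any one of the other 8, and 0 with a pseudocount of 0.1 or 5. Voom did not call POPTR_0019s13100 (-2.68, adjusted p = 0.147) and called 1 other gene, POPTR_0019s07690 (-3.52, adjusted p = 0.0488), named after its values were seen. No deposited description held the words ascorbate peroxidase, so that enzyme, which removes H2O2 with ascorbate, could not be named.

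Within each treatment, single libraries of a transgenic line and of wild type were then compared, with no replicate check. In the controls, the nucleoside phosphorylase POPTR_0019s07690 was at 107 FPKM in wild type, 2.15 in the antisense line and 2.10 in the overexpression line. The AUX/IAA gene POPTR_0005s23980 was at 39.8 FPKM in the wild type control and 0.332 in the overexpression control, a ratio of 0.00833 (95% counting interval 0.00399 to 0.0154). The cytochrome P450 POPTR_0014s03660 was at 11.4 FPKM in the wild type control and 0.374 in the antisense control. POPTR_0012s08970 was at 3.89 and 23.7 FPKM, and POPTR_0011s03140 at 0.107 FPKM (1 read) and 21.2, a ratio of 199 with a counting interval of 35.3 to 7906. After H2O2, where POPTR_0011s03140 had 0 reads in wild type, it was at least 33.0-fold higher in the antisense line and at least 117-fold higher in the overexpression line, against the floor of 3 reads in the wild type library. That floor leaves out the counting error of the transgenic library, with which the exact 95% counting intervals of the ratios reach down to 26.4 and 94.6.

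After H2O2 the expansin POPTR_0004s18840 was at 2.07 FPKM in wild type and 32.7 in the library labelled antisense H2O2, while POPTR_0009s12160 was at 114 and 6.43 and POPTR_0019s07690 at 9.44 and 0.164. In the overexpression line POPTR_0013s09960 was at 67.5 FPKM against 0.258 (1 read) in wild type, the acid phosphatase POPTR_0012s03910 at 2.66 against 261 and POPTR_0001s33270 at 7.64 against 492. After ASA the NAM gene POPTR_0001s02710 was at 1.56 FPKM in wild type and 42.9 in the library labelled antisense ASA, POPTR_0011s03140 at 0.329 and 15.6, POPTR_0017s13320, a subunit of the mitochondrial NADH-ubiquinone reductase, at 525 and 19.1, and the pyridoxal-phosphate-dependent transferase POPTR_0005s06130 at 67.8 and 2.06. In the overexpression ASA library the Tom22-type mitochondrial import gene POPTR_0014s18770 was at 100.6 FPKM against 1.49, POPTR_0013s09980 at 50.3 against 0.3002 (2 reads), POPTR_0003s02940 at 2.92 against 417 and POPTR_0001s33270 at 5.70 against 613.

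By group, the AUX/IAA median was -1.01 in the antisense control and -1.34 in the overexpression control, at the 0 and 0.01 percentiles of matched random lists, against -0.18 (44.7) in overexpression H2O2 and 0.21 (90.1) in overexpression ASA. Histones stood at -0.0912 in the overexpression control (percentile 69.7), 1.20 in overexpression H2O2 (100) and 1.01 in overexpression ASA (99.98). Over the same 3 libraries glutathione S-transferases stood at -0.0927 (66.5), -1.43 (0) and -1.14 (0.03) and cytochrome P450s at -0.35 (14.7), -1.27 (0.04) and -1.17 (0.71). Ribosomal proteins stood at 0.47 in the antisense control, -0.0799 in antisense H2O2 and 0.81 in antisense ASA, and at 0.87, 0.87 and 1.11 in the overexpression control, H2O2 and ASA libraries. Genes at 2-fold or more numbered 1072 in the antisense control (564 higher, 508 lower), 1998 in antisense H2O2 (1094, 904), 3550 in antisense ASA (1617, 1933), 2619 in the overexpression control (1477, 1142), 3003 in overexpression H2O2 (1031, 1972) and 3328 in overexpression ASA (1305, 2023). Median-ratio scaling moved the balance to 870 higher and 2558 lower in antisense ASA and 1332 and 1658 in overexpression H2O2. The larger side changed with it in the antisense control (459 and 593) and in the overexpression control (1058 and 1367).

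**Figure D3:**
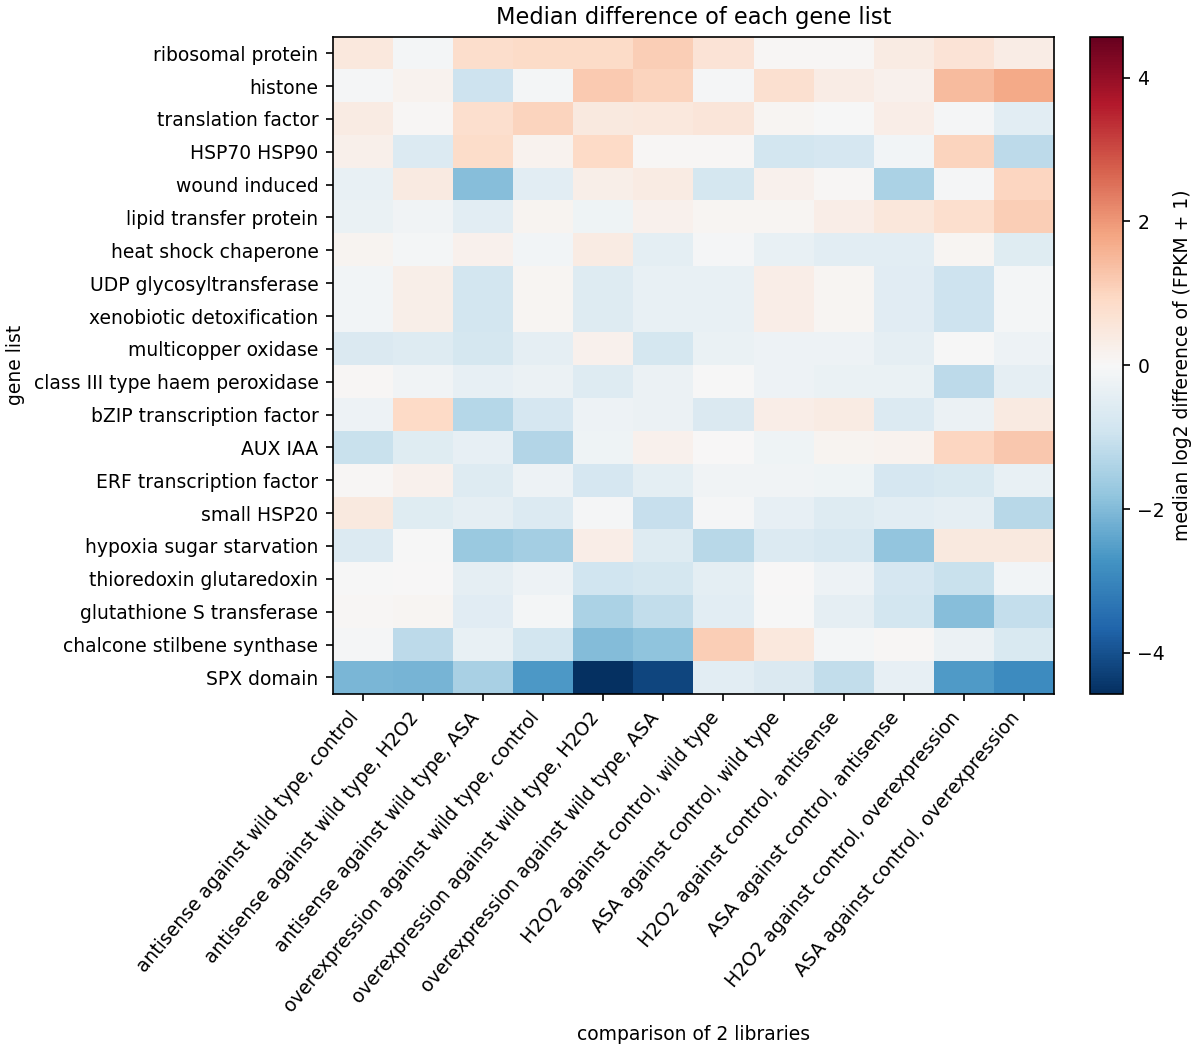
Colour gives the median log2 difference of (FPKM + 1) of each gene list (vertical axis) in each comparison of 2 libraries (horizontal axis), for the 20 lists past the threshold in at least 1 contrast. SPX genes are lowest in overexpression against wild type after H2O2 (-4.57) and histones highest in overexpression ASA against control (1.74).

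Each treated library was last compared with the control of its own line, again without a replicate check. In wild type, H2O2 and ASA libraries both had more of the glycoside hydrolase POPTR_0016s00460 (70.4 and 63.9 FPKM against 6.67) and less of the nucleoside phosphorylase POPTR_0019s07690 (9.44 and 7.84 against 107) and the peroxidase POPTR_0003s21610 (33.0 and 36.1 against 334). POPTR_0011s13350 of unknown function was at 40.5 FPKM after H2O2 against 4.65, and the zinc and iron permease POPTR_0018s05190 at 53.7 after ASA against 4.82. In the library labelled antisense H2O2, POPTR_0018s05190 was at 40.1 FPKM against 4.59, the C2-domain gene POPTR_0005s07760 at 13.1 against 2.21, POPTR_0009s12160 at 6.43 against 51.7 and POPTR_0019s13100 at 4.08 against 25.5. In the library labelled antisense ASA, POPTR_0015s15330 was at 31.3 FPKM against 2.29, POPTR_0001s02710 at 42.9 against 3.50, the DnaJ gene POPTR_0004s17810 at 5.16 against 142 and the universal stress protein POPTR_0005s01860 at 2.70 against 75.5.

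The overexpression line showed the largest differences from its own control of the 3 lines. The early nodulin POPTR_0004s19470 was at 606 FPKM after H2O2 and 708 after ASA against 14.1 in the control, and the hypoxia-induced domain gene POPTR_0019s08380 at 686 after H2O2 against 17.7. The wound-induced gene POPTR_0013s14410 was at 100.5 FPKM after ASA against 1.88. The FAD-linked oxidases POPTR_0254s00230 and POPTR_0011s16560 were at 888 and 1310 FPKM in the control, 8.07 and 13.0 after H2O2 and 7.12 and 11.7 after ASA. Histones had medians of 1.44 after H2O2 and 1.74 after ASA (percentile 100 for both), AUX/IAA genes 0.99 and 1.21 (100 for both) and glutathione S-transferases -1.95 and -1.10 (0 for both), whereas HSP70 and HSP90 genes stood at 1.01 after H2O2 (100) and -1.18 after ASA (0.01).

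Genes at 2-fold or more against the line's own control numbered 1579 in wild type H2O2 (819 higher, 760 lower), 1074 in wild type ASA (649, 425), 560 in antisense H2O2 (271, 289), 1922 in antisense ASA (744, 1178), 3637 in overexpression H2O2 (1355, 2282) and 3297 in overexpression ASA (1171, 2126). Median-ratio scaling gave 539 higher and 1385 lower in antisense ASA and 1762 and 1833 in overexpression H2O2. The larger side changed with it in wild type H2O2 (677 and 922) and in overexpression ASA (1661 and 1468). Across genes, the antisense ASA response correlated with the wild type H2O2 response at 0.714 and with the wild type ASA response at -0.0239, and the antisense H2O2 response with the wild type ASA response at 0.544 and with the wild type H2O2 response at 0.238.

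The authors' deposited tables list genes of each transgenic line against wild type within a treatment. In the authors' deposited tables the antisense line has 248 genes in the control (71 higher, 177 lower), 660 after H2O2 (435, 225) and 1391 after ASA (306, 1085), and the overexpression line 856 (303, 553), 1030 (424, 606) and 1224 (467, 757). Listed as lower in all 6 of the authors' deposited tables are 42 genes, among them the SPX genes POPTR_0006s06880, POPTR_0018s13140 and POPTR_0176s00240, the acid phosphatases POPTR_0009s12400, POPTR_0012s03910 and POPTR_0015s05350, the expansin POPTR_0018s10730 and the phosphoenolpyruvate carboxylase POPTR_0008s11330, and 0 are higher in all 6. Higher in the antisense line in all 3 treatments are 3 genes of the authors' deposited tables, named after their values were seen: myo-inositol-1-phosphate synthase POPTR_0005s08050 (deposited log2 fold of 1.58, 1.91 and 2.4999 in control, H2O2 and ASA), the late embryogenesis abundant gene POPTR_0010s01590 (1.32, 1.03 and 1.16) and POPTR_0012s02310 (1.16, 1.04 and 1.23).

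In the controls, the authors' deposited tables for both transgenic lines share 35 higher and 160 lower genes. Independent lists would share 0.921 and 4.19, and simulated unchanged lines against 1 shared wild type library 36.5 and 89.1. After H2O2 the tables share 20 higher and 107 lower genes (independent 7.90 and 5.84, simulated 141 and 108), and after ASA 30 and 306 (independent 6.12 and 35.2, simulated 121 and 323). After H2O2, 29 genes higher in the antisense line are lower in the overexpression line, and 10 go the other way. After ASA these numbers are 13 and 42, and in the controls 0 and 0. Only the lower genes of the controls (160) lie above the simulated value (89.1). The simulated spread is the residual of the main fit, which holds the scatter of line effects over treatments. Simulated genes were ranked by difference alone, not by the authors' test. A count below the simulated value therefore does not show that the overlap comes from the shared wild type library. Each pair shares 1 wild type library, so part of any excess may come from it. Of the antisense genes in the authors' deposited tables, 303 are higher after H2O2 and lower after ASA, whereas 5 are higher in both. The overexpression tables share 237 higher and 389 lower genes between H2O2 and ASA.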

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

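The tests of an exchange of antisense libraries, of the overexpression control and of a larger overexpression response were chosen only after the results had been seen, as was the limit of 0.5 (log2) used over 330 comparisons of list medians between lines. The 6 gene lists and the antisense libraries stand out because lines moved in opposite directions, and the overexpression libraries because of their distance from the others. None of these differences was tested, since each condition has 1 library. Values of gene lists are median log2 differences from the control of the same line, with their percentile among matched random lists in brackets. The antisense VQ-motif value and the wild type WRKY value lie within the range of most such lists.

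HSP70 and HSP90 chaperone genes stood at -0.77 (percentile 0) after H2O2 in the antisense line and 1.01 (100) in the overexpression line, a difference of -1.78 that was not tested. WRKY transcription factor genes stood at -0.52 (8.52) after H2O2 in wild type and 0.62 (99.92) in the overexpression line (difference -1.14, which was not tested). Auxin-responsive GH3 and SAUR genes stood at -0.65 (0.13) after ASA in wild type and 0.81 (98.5) in the overexpression line (difference -1.46, which was not tested). NAM and NAC transcription factor genes stood at 0.58 (99.86) after ASA in wild type and -0.78 (2.15) in the antisense line (difference 1.36, which was not tested). VQ-motif genes stood at 0.64 (98.6) after ASA in wild type and -0.54 (27.0) in the antisense line (difference 1.18, which was not tested). Wound-induced genes stood at -1.44 (0.015) after ASA in the antisense line and 0.97 (99.86) in the overexpression line (difference -2.41, which was not tested). The 4 of these that include the antisense line depend on the labels of its H2O2 and ASA libraries, which are in doubt. In the other treated antisense library HSP70 and HSP90 genes stood at -0.11, NAM and NAC genes at 0.0564, VQ-motif genes at 0.25 and wound-induced genes at 0.0585, and HSP70 and HSP90 genes stood at -1.18 in the overexpression ASA library.

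The libraries labelled antisense H2O2 and antisense ASA each resembled the other treatment of wild type: the H2O2 minus ASA difference correlated across genes at -0.838 between wild type and antisense, at 0.622 between wild type and overexpression and at -0.577 between antisense and overexpression, and whether the lines differ was not tested. Low read counts do not account for this, since among 7535 genes of at least 20 FPKM the first of these correlations was -0.917. An exchange of the antisense H2O2 and ASA libraries is a candidate explanation that requires this sign pattern (-0.838). It cannot be told apart from a different response of the antisense line, because the SD of the difference in the antisense line was 0.973 times that in wild type, and an exchange in both other lines would give the same signs. The libraries were kept as labelled throughout.

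The overexpression H2O2 and ASA libraries stood apart from the other 7 on the first principal component. Low read counts do not account for this, since among genes of at least 20 FPKM the overexpression H2O2 library had 2.09 times as many 2-fold changed genes as wild type H2O2, nor does gene length, as the larger rank correlation of the response with length was -0.0855. Their distance from the 6 wild type and antisense libraries does not involve the overexpression control. On a first component computed without that control, the gap to those 6 was 3.43 times their span, which describes the distance and tests no cause. For the distance from their own control, an unusual overexpression control stays open. That control lay with the other lines (-6.59) but differed from the wild type control at 1.61 times as many genes as wild type H2O2 did. Overexpression H2O2 differed at 2-fold or more at 4346 genes from the wild type control and 4129 from the antisense control. Both numbers are above the 3423 against its own control and the 1526 of wild type H2O2, and include the difference between the lines. These counts are over the 23350 tested genes, so they differ from those given above for genes with at least 1 FPKM in the higher library. A larger response of the overexpression line may also remain, and neither can be told apart from a difference between single cultures with 1 library per condition.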

How the results depend on the processing

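Voom and the fit without the antisense H2O2 and ASA libraries were chosen after the data had been seen, the gene lists in the wording of the descriptions after those had been read, and the other alternatives before. The main test already keeps treatment (or line) as a block, and the fit without the other factor is its unblocked form. The libraries carry no replicate numbers that could pair them further. The planned edgeR test on reads was not run, since the deposited values are FPKM, and voom on the recovered reads stands in its place. Depth sets the counting error and the floor of 0.153 to 0.175 FPKM for a gene of 1 kb, and says nothing of the scatter between cultures, which was not measured. Where a count changed, the cause was not tested, except that leaving out libraries leaves fewer residual degrees of freedom.

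For antisense against wild type (19 genes) the count was 3 with a pseudocount of 0.1, 0 with no filter, 7 at a mean of at least 5 FPKM, 9 without the other factor, 0 with only the 6 libraries compared, 6 by voom, and 0 without the 3 control, the 3 H2O2, the 3 ASA or the antisense H2O2 and ASA libraries. For overexpression against wild type (668) it was 398 with only the 6 libraries, 307, 20 and 57 without the control, H2O2 and ASA libraries, and 395 without the antisense H2O2 and ASA libraries. For antisense against overexpression (85) it was 44 at 5 FPKM, 287 without the other factor, 15 with only the 6 libraries, 209, 4 and 12 without the control, H2O2 and ASA libraries, 47 by voom and 0 without the antisense H2O2 and ASA libraries. Over the 3 lines (333) it was 206 at 5 FPKM, 553 without the other factor, 152, 5 and 12 without the control, H2O2 and ASA libraries, and 26 without the antisense H2O2 and ASA libraries. The single H2O2 call gave way to 0 with a pseudocount of 0.1 or 5, no filter, median-ratio or quantile scaling, no trend, no other factor, only the 6 libraries, and without the 3 libraries of any one line. Voom lost it too and called 1 other gene, with 0 shared. ASA had 2 genes by voom.

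Leaving out 1 library gave 0 to 30 genes for antisense against wild type, 70 to 1478 for overexpression against wild type, 10 to 2149 for antisense against overexpression, 33 to 1389 over the lines, 0 to 1 for H2O2, and 0 to 0 for ASA, for H2O2 against ASA and over the treatments. Camera lists numbered 4 to 8, 3 to 8, 3 to 6, 7 to 10, 7 to 13 and 4 to 12 in the 6 contrasts, and 0 in all 6 with an estimated correlation. Fry, which does not compare a list with other genes, passed 0 lists. All 47 list calls held with either pseudocount, median-ratio scaling and no trend, 46 with quantile scaling or only the 6 libraries, 45 at 5 FPKM and 42 without the other factor. Dropping the filter on low values was not run for lists, since 2975 of the 2976 annotated genes had been tested. The lists numbered 10 for antisense against wild type without the 3 H2O2 libraries, 4 for H2O2 without the 3 overexpression libraries, 6 for ASA without the 3 antisense libraries and 6 for H2O2 against ASA without the 3 wild type or the 3 overexpression libraries. Without the 3 overexpression libraries the AUX/IAA list for ASA (0.947) and, for H2O2 against ASA, glutathione S-transferases (0.460) and UDP-glycosyltransferases with the detoxification list (0.542) turned, and without the 3 wild type libraries ribosomal proteins did (0.339, and 2.08e-19 to 0.927 over leaving out 1 library).

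Genes at 2-fold or more between single libraries numbered, with a pseudocount of 0.1, 1964 (antisense control), 3119 (antisense H2O2), 3939 (overexpression control), and against own control 2608 (wild type H2O2), 2029 (wild type ASA), 1166 (antisense H2O2) and 3013 (antisense ASA). With a pseudocount of 5 the numbers against wild type were 367, 851 and 1688 (antisense control, H2O2, ASA) and 1066, 1329 and 1568 (overexpression), and against own control 640 and 384 (wild type H2O2, ASA), 182 and 871 (antisense), 1606 and 1367 (overexpression).

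The larger side also turned with a pseudocount of 5 in the antisense control (151 higher, 216 lower), the overexpression control (480, 586) and wild type H2O2 against control (258, 382), at 5 FPKM in the last (595, 655), and with a pseudocount of 0.1 in antisense ASA against wild type (2701, 2501).

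None of the 668, 85, 19 and 1 genes past the threshold changed sign in any alternative run, but calls were often lost. All of the 668, 19 and 1 genes had the same sign in all 3 pairs of libraries. Their sign could thus hardly turn, and its constancy adds no support. Of the 41 named results that had passed, the call was lost in 193 of 369 values from leaving out 1 library and in 180 of 570 from the other alternatives. The sign changed in 21 values of named genes that had not passed. Ranges given here are over leaving out 1 library. The AUX/IAA list turned without the overexpression control, with adjusted p from 0.000111 to 0.949 for H2O2 and from 8.22e-05 to 0.860 for ASA. For H2O2 against ASA, chalcone synthases (0.0187 to 0.933) turned without wild type H2O2, histones (6.37e-11 to 0.958) turned without overexpression ASA (0.945), and without overexpression H2O2 glutathione S-transferases (0.00150 to 0.259) turned at 0.116 and UDP-glycosyltransferases and the detoxification list of the same genes (0.00942 to 0.548) turned at 0.548. POPTR_0005s10090 ranged from -0.00991 (without antisense ASA) to 1.35 in antisense against wild type. The other values are log2 differences for H2O2 against ASA. Without wild type H2O2 the sign changed for POPTR_0010s21980 (-0.0935 to 0.46), POPTR_0013s01890 (-0.93 to 0.0307), POPTR_0010s23720 (-0.61 to 0.0583), POPTR_0003s17530 (-0.0478) and POPTR_0006s05450 (-2.99 to 0.19). Without overexpression ASA it changed for POPTR_0003s17530 (-0.0756 to 0.42) and POPTR_0006s05450 (0.0297). Without overexpression H2O2 it changed for POPTR_0019s15090 (-1.90 to 0.16), POPTR_0019s15100 (-1.60 to 0.11), POPTR_0008s17520 (-0.90 to 0.0694), POPTR_0016s00510 (-0.0208 to 1.08) and POPTR_0014s14300 (-1.90 to 0.20). Without the 3 overexpression libraries it changed for POPTR_0019s15090 (0.10), POPTR_0019s15100 (0.0103), POPTR_0006s02510 (0.0421), POPTR_0008s17520 (0.0176), POPTR_0016s00510 (-0.00388) and POPTR_0014s14300 (0.13). Without the 3 wild type libraries it changed for POPTR_0013s01890 (0.13) and POPTR_0006s05450 (0.43).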

Other observations

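The tests of shared SPX reads, of high wild type values and all counts of other splits were chosen only after the results had been seen. Several gene lists differed between single libraries, described here without a replicate check. Of these, only the hypoxia and haem peroxidase lists were also past the threshold in contrasts given above. Expansin and xyloglucan-modifying genes had a median of -0.90 in wild type H2O2 against control (21 of 27 lower, percentile 0 among matched random lists) and -1.21 in the library labelled antisense ASA (20 lower, percentile 0). Pectin enzymes stood at 0.70 in the library labelled antisense ASA against control (17 of 28 higher, percentile 100). Genes for hypoxia and sugar starvation stood at -1.81 there (9 of 9 lower, percentile 0.01) and at -1.26 in wild type H2O2 (9 of 9 lower, percentile 0.005). Late embryogenesis abundant genes, linked to desiccation tolerance, stood at 1.01 in the library labelled antisense H2O2 against wild type H2O2 (15 of 16 higher, percentile 99.96). F-box genes, which mark proteins for degradation, stood at -0.98 in wild type H2O2 against control (18 of 25 lower, percentile 0). In the overexpression H2O2 library haem peroxidases stood at -1.21 against control (15 of 18 lower, percentile 0.09).

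SPX-domain genes were lower in both transgenic lines. Reads moved between near-identical SPX copies do not account for this. Summed FPKM was at least 4.87 times higher in wild type than overexpression in each treatment, though copies may repeat a signal. High values in the wild type libraries alone stay open: in the controls the antisense sum was only 1.16 times the overexpression sum (204 and 176 FPKM against 858 in wild type), it stood higher after H2O2 (111 against 47.7) and ASA (154 against 38.4), and the list call between these lines (median 1.79) was lost without antisense ASA (adjusted p = 0.256) or overexpression ASA (0.0638), and had an adjusted p = 0.905 with an estimated correlation. A lower phosphate-starvation state of the overexpression culture is a candidate explanation: 23 other phosphate-related genes, fixed before their values were seen, had a median of -2.08 in overexpression against wild type, with 23 of 23 lower and 17 past the threshold (-1.23 in antisense, 23 lower, 2 past). Phosphate was not measured, and these genes come from the authors' own lists of changed genes, so the hypothesis remains open.

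With 3 libraries against 3 there are 10 splits, too few for a share under 0.05 (the smallest is 0.1). The real count and the highest of the other splits were 19 and 0 for antisense against wild type, 668 and 0 for overexpression against wild type, 85 and 0 for antisense against overexpression, 1 and 0 for H2O2 against control and 0 and 0 for ASA against control. In H2O2 against ASA they were 0 and 2024, the latter for wild type H2O2, antisense ASA and overexpression H2O2 against the rest. Among 100 of the 280 splits into 3 groups, only the real grouping gave as many genes as the 3 lines (333, highest other 81). Among 36 splits within treatments again only the real grouping did (highest other 42). The count thus goes with the grouping by line. Each genotype is a single cell line without replicates, so these splits cannot tell an effect of the constructs from a chance difference between cell lines or cultures. For the 3 treatments the real count is 0, which every split reaches (100 of 100, and 36 of 36 within lines), so these counts test nothing; the highest others were 640 and 1814. The splits with 1814 and 2024 genes exchange the antisense H2O2 and ASA libraries. They follow the structure already given by the correlation of -0.838, and add no evidence for an exchange over a different antisense response.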
